A study of Homo sapiens with 8 samples.

How the data were processed

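Total RNA from 8 cultures of HaCaT keratinocytes, 4 transfected with siETV4 and 4 with siNC in 35 mM glucose, was sequenced. Groups and replicate numbers were taken from the sample titles. The authors deposited a table of raw read counts per gene symbol, with 34415 symbols and 8 library columns, and a table of FPKM values (fragments scaled by gene length and library total) for the same symbols and libraries. The counts are whole numbers that sum to between 35057643 and 41657753 per library. The genome build hg38 and R 3.2.0 are named in the submitters' processing notes. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here, nor are the siRNA sequences. The deposited FPKM values were checked against the counts: each equals the count divided by the library's total count and by a gene length, and for 20584 of the 20585 genes above 0 that length was the same in every library within a relative tolerance of 1e-06. The FPKM values therefore hold no further normalization between libraries, and the counts were used for the main tests.

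At the mean depth 1 CPM corresponds to 40.1 counts. The pairwise Pearson correlation of log2 CPM between libraries was 0.973 to 0.987, and the chi-square statistic per degree of freedom of any pair of count columns was at least 10.4, so no library repeated another within sampling noise.

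Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10), which left 13572, and libraries were scaled by TMM factors. The siRNA was the only term of the model. Each gene was tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are siETV4 minus siNC, and their standard errors come from the same fit. CPM values use the TMM-scaled library sizes and are given as mean ± SD.

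The 29 gene lists, the tests and the rule for the genes that are named were fixed before the data were examined. Named genes are ETV4, ETV1 and ETV5, the 8 largest increases and 8 largest decreases among genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, the 3 smallest p values in each direction under the same conditions, and from each list up to 4 members past the threshold by smallest p, or its 2 most abundant members where fewer than 2 passed. Not every gene that the rule takes is named in the text. Any other gene named below is said to have been chosen after its values were seen. Lists with at least 5 tested members, 25 of the 29, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. Fry also gave a mixed test, which counts members that change in either direction.

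The alternatives fixed before the data were examined were RLE factors, library size alone, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, the replicate number as a block, each library left out in turn, other thresholds of the adjusted p, and limma-trend on the log2 of the deposited FPKM plus a pseudocount of 1 or 0.1. The FPKM tests kept genes with a mean of at least 0.5, or all genes. Alternatives chosen after the data had been examined were offsets that remove the trend of each library with GC content, or with GC content and length, by splines with 5 degrees of freedom, 1 surrogate variable (sva 3.50.0), and the offsets without siNC replicate 4. GC content came from the longest GENCODE v29 transcript of each symbol and length from the deposited FPKM. A value was found for 12771 of the 13572 tested genes (94.1%) and for all 32 called genes. Gene positions came from a RefSeq table of GRCh38.p14, the assembly that hg38 also names, in which 32094 of the 34415 symbols were found.

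The tests were checked on simulated counts drawn from the gene means, dispersions and library sizes of these 8 libraries, with 200 genes changed. In the simulated siETV4 against siNC comparison, edgeR, over 13370 genes, recovered 34.3% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 96.9% of those changed 4-fold, with 9 false calls. DESeq2, over 13572 genes, recovered 53.7%, 85.1% and 98.5% with 37 false calls. With the same GC content trend added to every simulated siNC library and to no siETV4 library, the uncorrected test over 13385 genes made 848 false calls. The offsets over 12644 genes made 11. In the sequenced libraries the trends also differ within each group, so these counts do not give the error rates of the tests reported below. In the simulated lists, made of random genes with independent counts, camera called the 1 raised list and 0 of the others. This check cannot show how camera fares with correlated members, and the estimated correlation reached 0.83 in the ribosomal protein list.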

Results

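RNA was sequenced from HaCaT cells, a spontaneously immortalized line of human epidermal keratinocytes, that spent 96 h in a high-glucose medium (35 mM) and received small interfering RNA (siRNA) by transfection for 48 h. In 4 cultures the siRNA was directed against ETV4 (siETV4), and in 4 it was a negative control (siNC). ETV4 is a transcription factor of the PEA3 group of the ETS family. The cultures are described by the submitters as independent biological replicates taken between passages 21 and 33. Each library held between 35057643 and 41657753 counts over 34415 gene symbols. Libraries at the usual 5.5 mM glucose were not analysed here, so the values compare the siRNAs within high glucose and say nothing on the effect of glucose.

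The first question was how far the siRNA lowered its target. ETV4 fell to 2.61 ± 0.547 CPM (SD, n = 4) in the siETV4 libraries from 28.2 ± 5.64 CPM (SD, n = 4) in the siNC libraries, a log2 fold change of -3.43 (SE 0.21) with an adjusted p of 4.64e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The siETV4 libraries held 129, 110, 76 and 116 ETV4 counts and the siNC libraries 1312, 1000, 1236 and 819, so no library overlapped the other group. The lowest siNC library, replicate 4, stood at 19.8 CPM, and the other siNC libraries at 29.7 to 32.0 CPM. ETV4 lies on chromosome 17 from 43527846 to 43546340 (GRCh38), a span shared in part with DHX8. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. ETV1 and ETV5, the other members of the PEA3 group, were low in both groups. ETV5 stood at 3.84 CPM in siETV4 and 5.29 CPM in siNC (log2 fold change -0.46, SE 0.16), and its edgeR adjusted p of 0.324 did not pass the threshold. It passed when siNC replicate 4 was left out (edgeR adjusted p 0.0453), but not with GC content and length trends removed (edgeR adjusted p 0.166). ETV1 stood at 0.804 and 1.04 CPM (log2 fold change -0.38, SE 0.39).

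**Figure D1:**
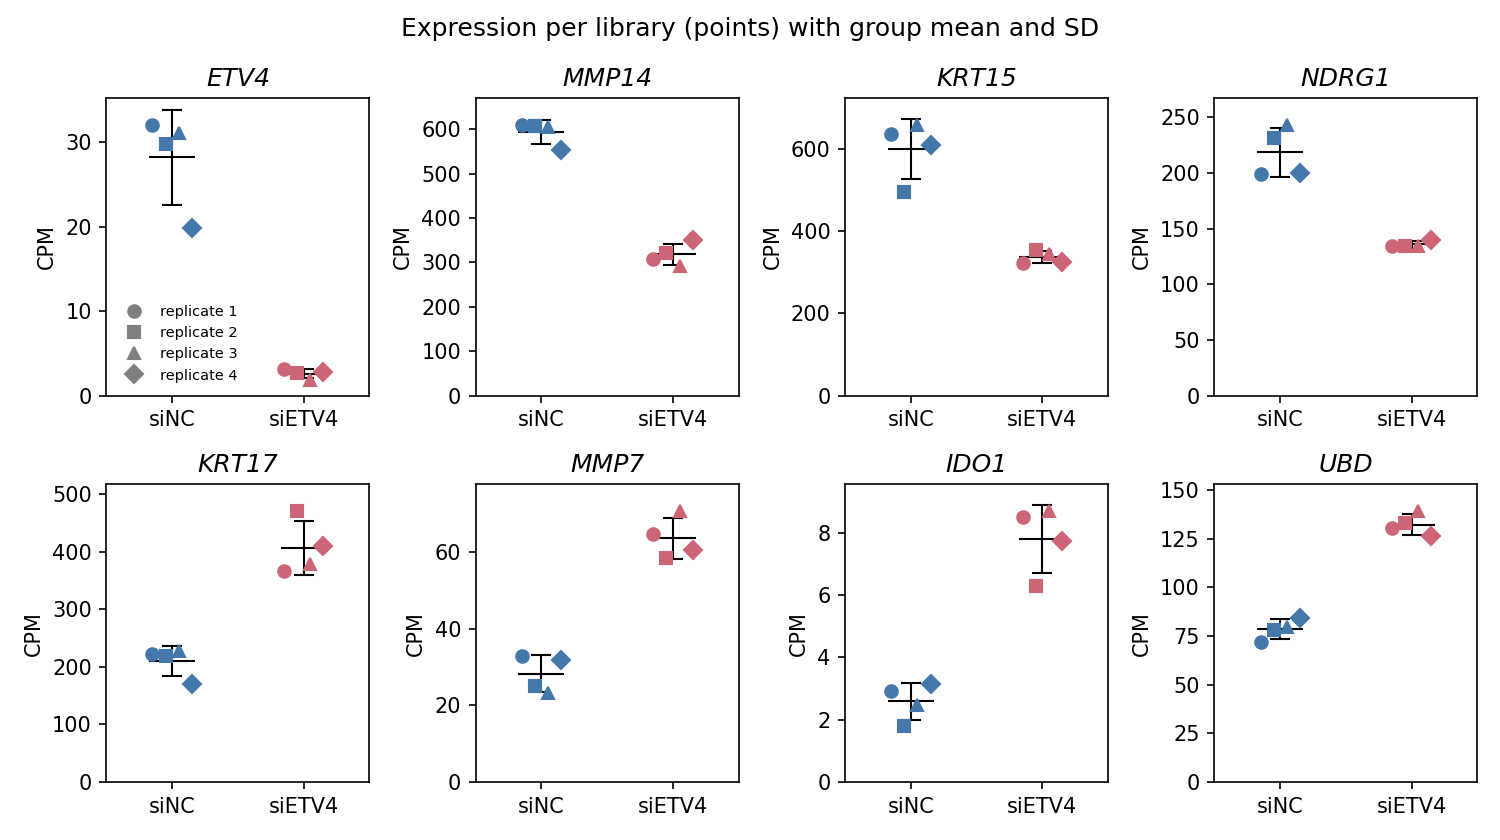
CPM (counts scaled to library size, y axis, starting at 0) of 8 named genes in the 4 siNC and 4 siETV4 libraries, with 1 point per library, its shape giving the replicate number, and the group mean with its SD in black. The groups do not overlap for any of the 8 genes, and siNC replicate 4 holds the lowest ETV4 of the siNC libraries at 19.8 CPM.

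The second question was which other genes differed between the siRNAs. Among them were 2 metalloproteinase genes and 2 keratin genes, of each pair 1 higher and 1 lower. MMP14, a membrane-bound metalloproteinase that cleaves collagen, fell from 594 ± 27.1 to 318 ± 24.5 CPM (SD, n = 4 each), a log2 fold change of -0.90 (SE 0.08) with an edgeR adjusted p of 0.00205, while MMP7, the secreted metalloproteinase matrilysin, rose from 28.3 ± 4.82 to 63.6 ± 5.42 CPM (log2 fold change 1.17, SE 0.13). KRT15, a keratin of basal keratinocytes, fell from 599 ± 72.8 to 336 ± 15.3 CPM (log2 fold change -0.83, SE 0.10), and KRT17, a keratin induced in wounded and inflamed epidermis, rose from 210 ± 26.1 to 406 ± 46.1 CPM (log2 fold change 0.95, SE 0.11). KRT17 has near-identical pseudogene copies, and how the authors' counting shared reads among them is not given in the sources used here. Across the 13572 genes tested, 32 passed an adjusted p of 0.05, 16 of them higher and 16 lower in siETV4. Of these, 13 differed by at least 2-fold, 9 higher and 4 lower.

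Several of the strongest increases were in genes that interferons induce. IFI27 rose from 1.24 ± 0.535 to 5.90 ± 1.43 CPM (SD, n = 4 each; log2 fold change 2.26, SE 0.31), BST2, which tethers budding virions, from 1.14 ± 0.243 to 3.37 ± 0.564 CPM (log2 fold change 1.57, SE 0.23), and IDO1, an enzyme of tryptophan breakdown, from 2.58 to 7.80 CPM (log2 fold change 1.59, SE 0.20). UBD, a ubiquitin-like modifier, reached 132 ± 5.22 CPM in siETV4 and 78.4 ± 5.04 CPM in siNC (log2 fold change 0.75, SE 0.08), and the edgeR adjusted p values of these 4 genes lay between 0.00611 and 0.0219. The T-cell costimulatory ligand CD86 (log2 fold change 1.68, SE 0.20), the acute-phase protease inhibitor SERPINA3 (1.63, SE 0.25), GLIPR1 (1.32, SE 0.20) and the chemokine CCL5 (1.07, SE 0.15) were also higher in siETV4.

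Among the decreases past the threshold, outside the keratins and metalloproteinases, CNTNAP1 had the lowest log2 fold change after ETV4 (-1.41, SE 0.23; 2.54 against 6.75 CPM). MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, followed with -1.06 (SE 0.17), then the zinc finger gene ZNF655 with -1.03 (SE 0.12). RASSF10 had a log2 fold change of -0.76 (SE 0.13). CD86 and GLIPR1 overlap ILDR1 and KRR1, which were also counted.

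The count of called genes depended on the libraries used: it was 10, 15, 9 and 16 without siETV4 replicates 1, 2, 3 and 4, 13, 10 and 13 without siNC replicates 1, 2 and 3, and 2327 without siNC replicate 4, of which 1654 were higher and 673 lower in siETV4. All 32 genes were among those 2327. With library size alone as the scaling, 16 genes were higher and 10 lower. Of the 22 named genes past the threshold, ETV4, MMP14, KRT15, KRT17, MMP7, ZNF655, UBD and CD86 passed in each of the 8 runs that left out 1 library. IFI27 was lost without siNC replicate 2 (edgeR adjusted p 0.0600) and IDO1 without siETV4 replicate 3 (edgeR adjusted p 0.0513). NDRG1 was lost without siETV4 replicate 1, siETV4 replicate 3 or siNC replicate 2 (highest edgeR adjusted p 0.0631), and the other 11 genes passed in 1 to 3 of the 8 runs.

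The libraries did not group by siRNA alone. The first principal component held 35.5% of the variance, and its gene loadings followed the GC content of transcripts (Spearman's rho 0.74 across genes, which are not independent replicates). The deviation of each library from the mean of all 8 correlated with GC content, across genes, at rho 0.55, 0.52 and 0.63 in siNC replicates 1 to 3 and at -0.60 in siNC replicate 4. In siETV4 replicates 1 to 4 it was -0.64, 0.20, -0.57 and 0.02. Across genes, the log2 fold change itself correlated with GC content at rho -0.55, and at -0.67 without siNC replicate 4. With the GC content and length trend of each library removed, a step chosen after the data had been examined, 208 genes passed, 102 higher and 106 lower, and the 32 genes were all among them.

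**Figure D2:**
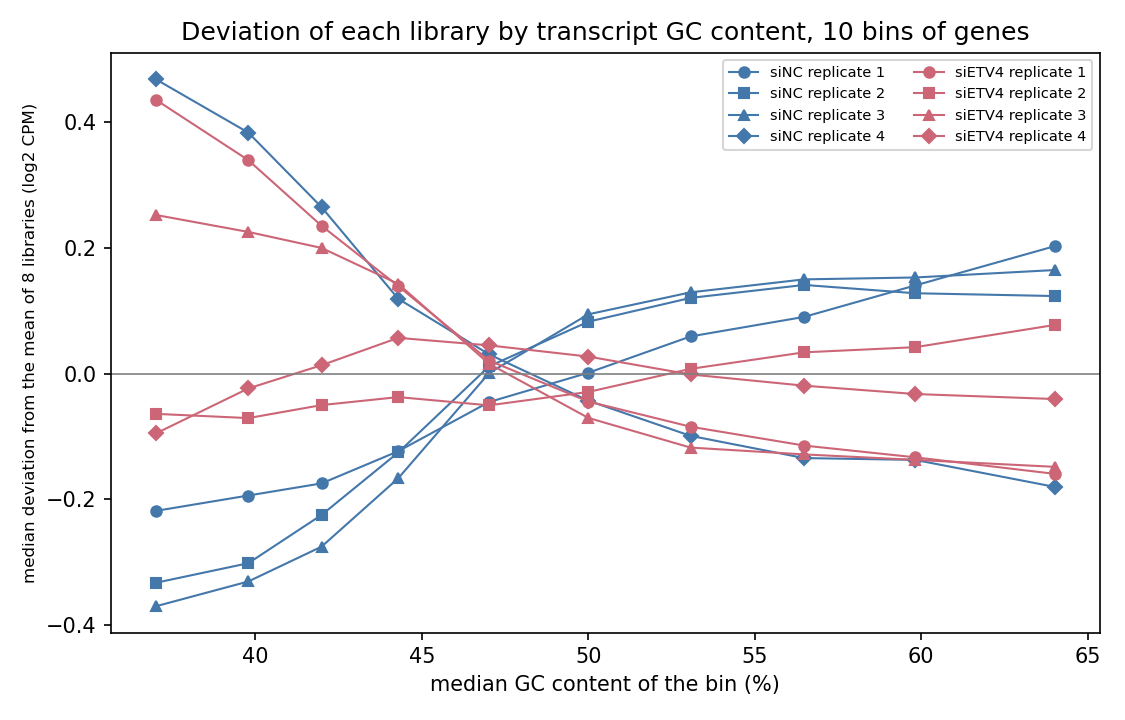
Median deviation of each library from the mean of the 8 libraries (y axis, log2 CPM) for 10 bins of genes by transcript GC content (x axis, percent), with 1 line per library. siNC replicate 4 runs with siETV4 replicates 1 and 3 from high values at low GC content to low values at high GC content, and siNC replicates 1 to 3 run the other way.

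The third question was whether genes of known pathways moved together, for which 29 gene lists had been fixed before the data were examined. Type I interferon genes formed the list with the largest median change. Of its 29 tested members, 3 passed the threshold, all higher in siETV4 (IFI27, BST2 and IFI6), and 26 did not pass. Adjusted over the list alone, 15 were higher and 0 lower. In all, 25 members had a positive log2 fold change, with a median of 0.60, and camera called the list (adjusted p 3.82e-16, and adjusted p = 0.00177 with an estimated correlation). The list's median deviation was 0.13 to 0.44 in the siETV4 libraries, -0.33 to -0.43 in siNC replicates 1 to 3 and -0.09 in siNC replicate 4. IFI6 had a log2 fold change of 1.03 (SE 0.18). Over all genes, 18 members of the list passed without siNC replicate 4 and 9 with the GC content and length trends removed, all higher.

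NF-kB and inflammatory cytokine genes were also higher as a list (median log2 fold change 0.42, camera adjusted p 2.33e-08, and adjusted p = 0.00673 with an estimated correlation). Of 25 members tested, 1 rose past the threshold over all genes, the chemokine gene CCL5, at 14.4 ± 1.38 against 6.87 ± 1.00 CPM (SD, n = 4 each). Adjusted over the list alone, 9 were higher and 0 lower. The most abundant members, TNFAIP2 (log2 fold change -0.07) and NFKBIA (-0.01), did not pass. Over all genes, 10 members passed without siNC replicate 4 and 6 with the GC content and length trends removed, all higher. The list's median deviation was -0.10 in siNC replicate 4 and -0.15 to -0.28 in the other siNC libraries. These 2 lists were the only calls among the 25 tested lists that camera kept with an estimated correlation.

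Cholesterol biosynthesis genes were lower in siETV4 (median log2 fold change -0.28, camera adjusted p 4.46e-08), although with adjusted p = 0.0832 with an estimated correlation. Of 24 members, 1 fell past the threshold over all genes and 11 adjusted over the list alone, with 0 higher. Over all genes, 12 were lower and 1 higher without siNC replicate 4. With the GC content and length trends removed 7 were lower and 0 higher. FDFT1, the squalene synthase gene, had a log2 fold change of -0.38 and passed only without siNC replicate 4 among the runs that left out 1 library (edgeR adjusted p 0.0149). With the GC content and length trends removed FDFT1 did not pass (edgeR adjusted p 0.0660). In siNC replicates 4 and 1 the list's median deviation was -0.00 and 0.01, and in siNC replicates 2 and 3 it was 0.27 and 0.22.

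Hypoxia response genes were lower as well (median log2 fold change -0.15, camera adjusted p 6.85e-04, and adjusted p = 0.143 with an estimated correlation). NDRG1 was the single member of 19 past the threshold, at 136 ± 2.87 against 218 ± 22.1 CPM (log2 fold change -0.69, SE 0.09, edgeR adjusted p 0.0114). Adjusted over the list alone, 5 were lower and 1 higher. The list's median ranged from -0.19 to -0.09 when 1 library was left out, the smallest without siNC replicate 2. DDIT4 had a log2 fold change of -0.47 and ERO1A of 0.23, neither past the threshold with all 8 libraries. Without siNC replicate 4 both passed (edgeR adjusted p 0.00569 and 0.0210), as DDIT4 did with the GC content and length trends removed (edgeR adjusted p 0.0253). With these trends removed ERO1A did not pass (log2 fold change 0.0008, edgeR adjusted p 0.998). Glucose uptake and glycolysis genes were called lower (median -0.18, camera adjusted p 0.0237, and adjusted p = 0.321 with an estimated correlation). None of the 28 members passed over all genes, against 4 lower and 2 higher adjusted over the list alone. GAPDH stood at a log2 fold change of -0.30 and PKM at -0.13, and GAPDH passed without siNC replicate 4 (edgeR adjusted p 0.0229). With the GC content and length trends removed GAPDH did not pass (edgeR adjusted p 0.107), and the call of the glycolysis list was lost (camera adjusted p 0.153).

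**Figure D3:**
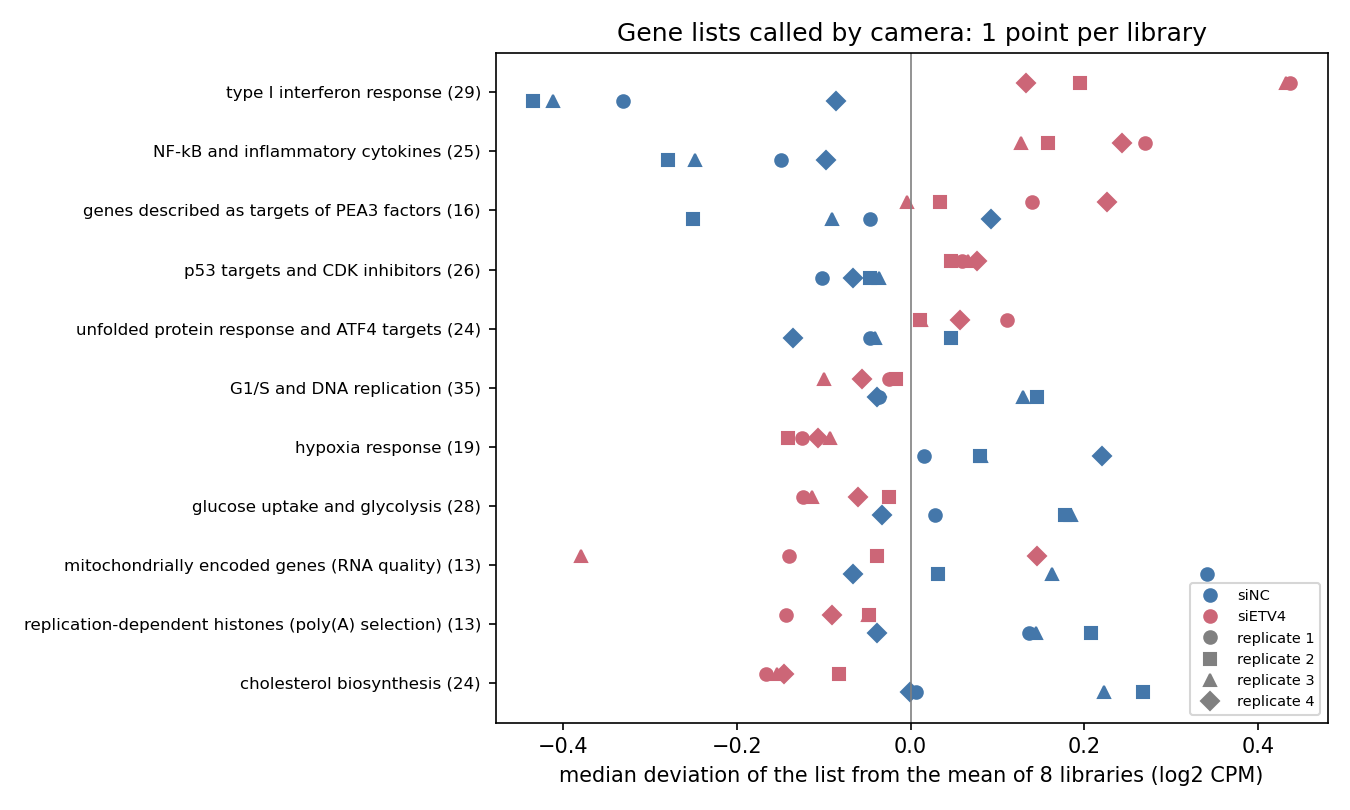
Median deviation from the mean of the 8 libraries (x axis, log2 CPM) of the tested members of each of the 11 gene lists called by camera (y axis, number of members in brackets), with 1 point per library coloured by siRNA and shaped by replicate number. For the interferon list the siETV4 libraries lie at 0.13 to 0.44 and the siNC libraries at -0.43 to -0.09.

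Genes described elsewhere as targets of PEA3 factors did not fall as a list. Of 16 members, 1 rose (MMP7) and 1 fell (MMP14), with 3 higher and 1 lower adjusted over the list alone, and the median log2 fold change was 0.19 (camera adjusted p 0.0480, and adjusted p = 0.272 with an estimated correlation). With library size alone as the scaling, camera did not call it (adjusted p 0.0731). Without siNC replicate 4 camera called it (adjusted p 0.0393), with 5 members higher and 1 lower past the threshold. With the GC content and length trends removed 4 were higher and 1 lower, and the median was 0.24. Camera called it there too (adjusted p 2.07e-04, and adjusted p = 0.240 with an estimated correlation). The p53 target and CDK inhibitor list was called higher with a median of 0.09 (camera adjusted p 0.0388, and adjusted p = 0.152 with an estimated correlation). None of its 26 members passed over all genes and 1 was higher adjusted over the list alone, and its most abundant members were PHLDA3 (log2 fold change -0.07) and CDKN1A (0.16), of which CDKN1A passed with the GC content and length trends removed (edgeR adjusted p 0.0370). With these trends removed 3 members of the p53 list were higher past the threshold and 0 lower. Camera then called the list (adjusted p 7.44e-04, and adjusted p = 0.0480 with an estimated correlation). The unfolded protein response and ATF4 list had a median of 0.05 (camera adjusted p 0.0480, and adjusted p = 0.321 with an estimated correlation), with 0 of 24 members past the threshold and 1 higher adjusted over the list alone. With the GC content and length trends removed its median was 0.09, with 1 member higher and 0 lower. Camera kept the call (adjusted p 0.00416, and adjusted p = 0.268 with an estimated correlation). SLC7A5 and SLC3A2, which form an amino acid transporter, had log2 fold changes of -0.03 and -0.02.

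For the cell cycle, the G1/S and DNA replication list was called lower by a small median of -0.06 (camera adjusted p 0.0388, and adjusted p = 0.346 with an estimated correlation). None of its 35 members passed over all genes and 1 was lower adjusted over the list alone, with MCM7 at a log2 fold change of -0.28 and MCM4 at -0.06. The G2/M and mitosis list was not called (median -0.00, camera adjusted p 0.791), with 0 of 35 members past the threshold either way of adjusting. Its median was 0.18 without siNC replicate 4 (camera adjusted p 0.232), with 8 members higher and 4 lower past the threshold. With the GC content and length trends removed the median was -0.09, with 1 member lower and 0 higher. Camera then called the list (adjusted p 0.00597, and adjusted p = 0.518 with an estimated correlation). CDC20 had a log2 fold change of -0.25 and TPX2 of -0.12. MCM7 and CDC20 passed when siNC replicate 4 was left out (edgeR adjusted p 0.0234 and 0.0230). Neither passed with the GC content and length trends removed (edgeR adjusted p 0.244 and 0.227).

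The mitochondrially encoded genes, listed for RNA quality, and the replication-dependent histones, listed for poly(A) selection, were called lower by camera at the preset correlation. All 13 mitochondrially encoded genes had negative log2 fold changes (median -0.22, camera adjusted p 9.09e-04, and adjusted p = 0.515 with an estimated correlation), with 0 past the threshold either way of adjusting. The list's median deviation was -0.38 to 0.15 in the siETV4 libraries and -0.07 to 0.34 in the siNC libraries, so the groups overlapped. Its median log2 fold change ranged from -0.31 to -0.12 when 1 library was left out. Their share of counts was 3.38 to 4.50% in siETV4 and 3.98 to 5.04% in siNC, and COX1 and COX3 had log2 fold changes of -0.22 and -0.14. The replication-dependent histone list was lower with a median of -0.23 (camera adjusted p 0.0480, and adjusted p = 0.203 with an estimated correlation), with 0 of 13 members past the threshold. H2BC12 had a log2 fold change of -0.24 and H1-2 of -0.08, and H2BC12 passed without siNC replicate 4 (edgeR adjusted p 0.0230). With the GC content and length trends removed H2BC12 did not pass (edgeR adjusted p 0.573), and the call of the histone list was lost (camera adjusted p 0.0929).

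Of the called lists, 6 also lost their call when 1 library was left out, here with the camera adjusted p without it. The PEA3 target list did so without siETV4 replicate 4 (0.112) or siNC replicate 2 (0.0868), and the G1/S list without siETV4 replicate 4 (0.0964), siNC replicate 2 (0.108) or siNC replicate 4 (0.0542). The p53 list did so without siETV4 replicate 2 (0.0517), siETV4 replicate 4 (0.0964) or siNC replicate 4 (0.126), and the glycolysis list without siETV4 replicate 1 (0.0582), siETV4 replicate 4 (0.0808) or siNC replicate 2 (0.0626). The unfolded protein response list did so without siETV4 replicate 1 (0.0966), siETV4 replicate 4 (0.0971) or siNC replicate 4 (0.232). Its median was -0.03 without siNC replicate 4, against the direction of the call, although 7 members were then higher past the threshold and 0 lower. The histone list did so without siETV4 replicates 1, 2 or 4 (0.0582, 0.0517 and 0.102) or siNC replicates 2 or 4 (0.0907 and 0.0920). Over these runs the median of the PEA3 target list ranged from 0.12 to 0.35, that of the G1/S list from -0.12 to -0.05 and that of the p53 list from 0.07 to 0.16, each at its largest without siNC replicate 4.

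The study's title names keratinocyte migration, oxidants and Akt, and lists on these were not called by camera with all 8 libraries and no correction. The lists read mRNA levels only, so they do not measure cell movement, oxidant levels or the phosphorylation of Akt. In the wound-edge and migration list (median log2 fold change 0.10, camera adjusted p 0.0960), 2 of 30 members rose, KRT17 among them. Adjusted over the list alone, 2 members were higher and 3 lower. Fry's mixed test called the list (adjusted p 6.13e-05). With the GC content and length trends removed camera called it (median 0.06, adjusted p 0.00252, and adjusted p = 0.240 with an estimated correlation). Without siNC replicate 4 the median was 0.17 (camera adjusted p 0.173), with 8 members higher and 4 lower past the threshold. The PI3K-Akt component list had a median of -0.05 (camera adjusted p 0.256), with 0 of 32 members past the threshold and 1 lower adjusted over the list alone, AKT1 at a log2 fold change of -0.06 and EGFR at 0.04. The NRF2 and antioxidant list had a median of -0.07 (camera adjusted p 0.119), with 0 of 32 past the threshold and 2 higher and 3 lower adjusted over the list alone, FTH1 at 0.10 and TXN at -0.15. Without siNC replicate 4 camera called it (median -0.12, adjusted p 0.0376, and adjusted p = 0.504 with an estimated correlation). The NADPH oxidase list had a median of -0.04 (camera adjusted p 0.190), with 0 of 7 past the threshold either way, CYBA at 0.01 and DUOXA1 at -0.14.

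Keratinocyte state lists did not move in 1 direction as a whole. Fry's mixed test called the basal list (adjusted p 0.00643) and the terminal differentiation and mesenchymal lists (adjusted p 0.00698 each). It did not call the epithelial junction list (adjusted p 0.0977). The basal and hemidesmosome list (median 0.00, camera adjusted p 0.230) held 1 gene that fell, KRT15, among 18, also when adjusted over the list alone, with KRT5 at -0.19 and CAV1 at 0.16. The terminal differentiation list (median -0.06, camera adjusted p 0.892) had 0 of 19 past the threshold and 1 lower adjusted over the list alone, with KLK5 at -0.09 and DMKN at -0.10. The median of the terminal differentiation list was 0.06 without siNC replicate 4 and 0.06 with the GC content and length trends removed, and that of the basal list was -0.06 and 0.09. In these lists, as in the ETS family and YAP/TAZ lists, median and test differed in sign. Epithelial junction genes (median 0.02, camera adjusted p 0.958) had 0 of 28 past the threshold either way, with JUP at -0.16 and CDH3 at -0.01, and mesenchymal genes (median -0.00, camera adjusted p 0.958) had 0 of 16 past it and 1 higher adjusted over the list alone, with THBS1 at 0.21 and FN1 at -0.28.

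The remaining lists were not called by camera with all 8 libraries and no correction. ETS family members other than ETV4 (18 tested, median 0.04, camera adjusted p 0.845), MAPK feedback and immediate early genes (21 tested, median -0.11, camera adjusted p 0.111), oxidative phosphorylation genes (35 tested, median -0.09, camera adjusted p 0.157) and cytosolic ribosomal protein genes (73 tested, median -0.08, camera adjusted p 0.119) had no member past the threshold either way of adjusting. Without siNC replicate 4 the MAPK list had a median of -0.20 (camera adjusted p 0.05003, not under the threshold) and the ETS list of 0.10, and with the GC content and length trends removed these were -0.03 and -0.02. Without siNC replicate 4 camera called the oxidative phosphorylation list (median -0.17, adjusted p 0.0121, and adjusted p = 0.780 with an estimated correlation) and the ribosomal protein list (median -0.15, adjusted p 5.38e-04, and adjusted p = 0.802 with an estimated correlation). With the GC content and length trends removed it called the oxidative phosphorylation list (adjusted p 0.0188, and adjusted p = 0.636 with an estimated correlation). YAP/TAZ targets (23 tested, median -0.01, camera adjusted p 0.415) had none past it over all genes and 2 higher adjusted over the list alone. Its median was -0.06 without siNC replicate 4 and 0.06 with the trends removed. Among the most abundant members, ELF3 had a log2 fold change of -0.10, ELF4 of -0.15, JUNB of -0.13, EMP1 of -0.03, IGFBP3 of -0.07, MYOF of 0.20, ATP5F1B of -0.07, RPS2 of -0.21 and RPL8 of -0.14. Of these, MYOF passed without siNC replicate 4 (edgeR adjusted p 0.0438), but not with the GC content and length trends removed (edgeR adjusted p 0.226). Markers of fibroblasts, melanocytes, leukocytes and endothelium had 3 tested members each, too few for the list test. None of these markers passed over all genes and 1 fibroblast marker was higher adjusted over the list alone. The most abundant of them were CD68 at 22.5 against 20.2 CPM, CDH5 at 18.5 against 14.8 CPM, MITF at 5.64 against 4.28 CPM and COL1A1 at 3.47 against 4.24 CPM in siETV4 and siNC.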

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

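The tests of the GC content trend and of exchanged labels in siNC replicate 4, and the repeat of the admixture test in the other siNC libraries, were chosen after the result was seen. The other tests in this part were set before theirs.

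Within the siNC group, replicate 4 stood apart from the other libraries. Its 100 most abundant genes took 21.96% of the counts, against 24.6 to 24.9% in the others. Across genes, its deviation from the mean of all libraries correlated with GC content at -0.598, against 0.523 to 0.631. MMP14 stood at 553 CPM against 605 to 609 CPM, CDC20 at 517 against 644 to 650 CPM, and KRT17 at 171 against 219 to 227 CPM. Within the siETV4 group it was replicate 2 that stood apart, with KLK5 at 322 CPM against 261 to 270, DMKN at 100.4 against 74.4 to 78.8, TXN at 1308 against 1106 to 1118, AKT1 at 262 against 211 to 218, GAPDH at 7385 against 6094 to 6222 and RPL8 at 4414 against 3183 to 3274 CPM. NDRG1 was higher in siETV4 replicate 4, at 140 CPM against 134 to 135 CPM, and COL3A1 was lower in siNC replicate 3, at 0.126 CPM against 0.505 to 0.581 CPM. These are 13 of 184 groups of 4 libraries examined, and chance alone marks about 1 in 20.

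An exchange of labels between siNC replicate 4 and a siETV4 library was excluded by ETV4, which stood 6.40 times above the highest siETV4 library. The GC content trend of -0.598, which runs with siETV4 replicates 1 and 3, remains a possible explanation for the distance of this library, and without it 2327 genes were called uncorrected and 815 with the trends removed, of which 475 were in both, so part of the 2327 calls may follow GC content and length. Admixture of siETV4 material would need a share of 0.227 to give the ETV4 level of this library, and the median share over 34 other genes was 0.155 (bootstrap SE 0.0665). For the other siNC libraries the same median ranged from -0.104 to 0.0930, below the 0.155 of replicate 4 but with SEs up to 0.0809. A culture with less ETV4 mRNA could shift the same genes by such a share too. The test therefore cannot tell such a culture from admixture. The labels give no group that would set this library apart, and no biological explanation was tested.

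The 8 libraries can be split into 4 and 4 in 35 ways. A count of at least 32 genes was reached by 3 of the 35, the real split included, so chance was not excluded by the count alone. The highest other split called 4543 genes, and it exchanged siETV4 replicate 2 with siNC replicate 4. The next called 1768, and it exchanged siETV4 replicate 4 with siNC replicate 4. Splits that call so many more genes than the real one point to a structure of the samples, here with siNC replicate 4 on the siETV4 side. For genes with a fold of at least 2, 3 of the 35 splits reached the real count of 13 (highest other 81), and with GC content and length trends removed 3 of the 35 reached the real count of 208 (highest other 697). For gene lists, 2 of the 35 reached the real count of 11 (highest other 15), so chance was not excluded for these counts either.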

How the results depend on the processing

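The alternatives on GC content, length and surrogate variables were chosen after the data had been examined. The ETV4 log2 fold change kept its direction and its side of the threshold in every alternative run, at -3.57 to -3.29 over the libraries left out in turn and -2.49 to -3.43 elsewhere. Of 1718 alternative values of the 75 other named genes, 1589 kept their side of the threshold, 101 of 19 genes no longer passed, 28 of 13 genes newly passed, and 0 reversed. Of 198 alternative values of the 11 called lists, 151 kept their side, 47 of 9 lists no longer passed, and 0 passed in the other direction. The median of the unfolded protein response list did turn to -0.03 without siNC replicate 4, where its call was lost. In that run 7 of its members were higher past the threshold and 0 lower.

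The count of 32 genes moved with most choices, and the cause was not tested except where stated. It was 54 without a filter, 167 with DESeq2, 59 with limma-trend on FPKM at either pseudocount, 9 at an adjusted p under 0.01 and 60 at one under 0.1. It was 121 with GC content removed, 208 with GC content and length removed, 443 with 1 surrogate variable and 815 with GC content and length removed and siNC replicate 4 left out. Leaving out 1 library gave 9 to 2327 genes, the highest without siNC replicate 4 and at most 16 otherwise, where fewer samples are 1 cause. The 13 genes of at least 2-fold became 38 with DESeq2, 7 with unfiltered FPKM, 23 with GC content and length removed, 38 with 1 surrogate variable, 38 with the removal and siNC replicate 4 left out, and 5 to 98 with 1 library left out. The 11 lists became 2 with an estimated correlation, 4 with it and the trends removed, and 5 to 14 with 1 library left out. With fry there were 9. The PEA3 target list (fry adjusted p 0.0560) and the mitochondrially encoded genes (fry adjusted p 0.338) were not among them. Fry's mixed test, which gives no direction, called 13 of the 25 lists. The share of genes higher in siETV4 was 16 of the 32 in the analysis reported, 61.5% with library size alone and 71.1% without siNC replicate 4.

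The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.09, 0.30, -0.14 and -0.19, and not every library correlated best with its own number. With the replicate number as a block, 4 genes were called, 3 of them at 2-fold or more.

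Every library held 35057643 counts or more. At the spread of these cultures the simulated comparison recovered 34.3% of 1.5-fold changes, so a gene that did not pass may still have changed by that much, and the 167 genes of DESeq2 include all 32.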

Other observations

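The 4 gene groups in the next paragraph, their tests and the single genes named outside the fixed rule were chosen after single genes had been seen, so they are hypotheses from the same data. The other tests in this part were set before their results were seen.

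Beyond the fixed lists, all 4 groups picked from genes already seen to differ also passed the list test. Members just short of the threshold, such as SERPINB2 (edgeR adjusted p 0.0547), stayed in them. The p values of the groups are therefore not independent of that choice. Every gene already called or listed was left out of the groups first, so no remaining member could pass the threshold alone. Without those genes, antimicrobial and protease inhibitor genes were higher in siETV4 (14 of 15 tested members positive, median log2 fold change 0.37), with an adjusted p of 0.00142 by camera with an estimated correlation over the 4 groups. Among them, LCN2, which binds bacterial siderophores, stood at 571 against 443 CPM, SERPINB2 at 202 against 145 CPM and SERPINB3 at 5.54 against 1.71 CPM, in none of which the gene alone passed the threshold. Complement genes (9 of 14 positive, median 0.32, CFB at 50.4 against 30.8 CPM) and interferon-gamma response and antigen presentation genes (24 of 35 positive, median 0.05, GBP2 at 11.2 against 6.29 CPM) each had a camera adjusted p of 0.0286. In the interferon-gamma group 11 members were negative, IRF1 among them at 175 CPM in siETV4 against 208 CPM in siNC. Fatty acid synthesis genes were lower (13 of 18 negative, median -0.15, camera adjusted p 0.0286), with FASN at 350 against 528 CPM and SREBF1 at 249 against 327 CPM. With the GC content and length trends removed, some members did pass the threshold. These were 5 antimicrobial, 2 complement and 4 interferon-gamma response genes, all higher, and 2 fatty acid synthesis genes, both lower. SCD, the stearoyl-CoA desaturase, is among the 32 called genes, at 1253 ± 119 against 1833 ± 50.4 CPM (SD, n = 4 each; log2 fold change -0.55, SE 0.09).

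Some large differences fell short of the threshold. DNAJC13, an endosomal co-chaperone, stood at 15.0 ± 5.81 CPM in siETV4 and 51.0 ± 26.0 CPM in siNC (SD, n = 4 each; log2 fold change -1.77, SE 0.34, edgeR adjusted p 0.0690), and the collagenase MMP13 at 20.9 ± 4.94 against 6.80 ± 3.81 CPM (log2 fold change 1.62, SE 0.33, edgeR adjusted p 0.0882).

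The higher interferon and inflammatory lists are a pattern to follow up. A trend with GC content and length was not the whole cause, since with the trends removed the list medians were 0.457 and 0.351, from 0.60 and 0.42, and camera kept both calls with an estimated correlation. No other of the 35 splits gave as large a median, so the real split was 1 of 35 for each list, the smallest share possible, with 0.588 for interferon and 0.275 for inflammatory genes as the highest others. Chance is left open for both, because the lists were put to this test after camera had called them and the share would not pass over several lists. Loss of ETV4 and a response to the siETV4 duplex itself both remain possible explanations, untested here because the 8 libraries hold a single ETV4 siRNA treatment.

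The lower cholesterol and hypoxia lists are another such pattern. With the GC content and length trends removed, their medians were -0.209 and -0.188, from -0.28 and -0.15, and camera at the preset correlation kept both, which argues against those trends as the whole cause. For hypoxia 1 of the 35 splits gave a median as large, the real one, with 0.147 as the highest other, and for cholesterol 2 did, with 0.280 as the highest other, so chance was not excluded for cholesterol. For hypoxia it stays open for the same reason, and the real median of -0.152 ranged from -0.187 to -0.0926 when 1 library was left out. With an estimated correlation neither list passed (adjusted p 0.0832 and 0.143 by camera), and with the trends removed as well cholesterol still did not (0.0642) while hypoxia did (0.0480).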
